A study of Mus musculus with 16 samples.

How the data were processed

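Gene expression was measured in E14 cells, a line of mouse embryonic stem cells, which carried a stably expressed short hairpin RNA (shRNA) from a lentiviral vector. The hairpin was either a control (sh-Control) or directed against Sirt1 (sh-SIRT1), the gene of an NAD-dependent deacetylase. The cells grew in medium with leukemia inhibitory factor, a cytokine that keeps them undifferentiated, and received ethanol as vehicle or 20 nM retinoic acid (RA; its isomer is not given in the sources used here) for 2 days. The labels gave 16 arrays in 4 groups: sh-Control vehicle (n = 3), sh-SIRT1 vehicle (n = 3), sh-Control RA (n = 4) and sh-SIRT1 RA (n = 6). The design text speaks of 3 pairs of sh-Control and sh-SIRT1 cells with duplicates, but which RA arrays are duplicates of each other is not given. P-values therefore measure the spread between these arrays, which may be partly technical. Within groups, sh-Control RA arrays 3 and 4 differed least, with an SD of the log2 difference over genes of 0.214, against 0.269 to 0.736 for the other pairs of arrays, and all arrays were counted as separate samples.

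The deposited files hold 1-colour (Cy3) intensity values of Agilent Whole Mouse Genome arrays with 45018 spots, 43379 of them not controls. Per the submitters' processing notes the authors used Feature Extraction 9.5, and per the file headers its version was 9.5.3.1. Per the file headers, the processed intensity had a spatial trend removed and a multiplicative trend corrected, surrogate values stood in for signals too close to background, and no other background correction was switched on. Probe positions in the headers refer to the mouse build mm7, the only build used here; the exon or untranslated region in which a probe lies was not analysed here. The series matrix held values exactly equal to these processed intensities on all 45018 spots of each array. Its column medians were 46.0, 52.3 and 62.5 for sh-Control vehicle, 48.4, 58.9 and 63.1 for sh-SIRT1 vehicle, 78.5, 70.1, 74.2 and 74.0 for sh-Control RA, and 75.5, 64.6, 68.7, 79.2, 91.4 and 87.9 for sh-SIRT1 RA, so its scale is linear, with no centring and no ratio.

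Control spots were left out and spots with an outlier mark (87 to 131 per array) were set to missing. The log2 of the processed intensity minus the 75th percentile of its array gave the expression value, and spots of the same probe were averaged (245 probe names were spotted more than once). A probe was kept if it was well above background on all arrays of at least 1 group, which left 26375 of 41174 probes. Names were taken from a RefSeq gene table through the accession for 17567 of these probes and otherwise from the files. Of several probes of a gene, the probe with the highest mean over all arrays stood for it, which gave 18282 genes, 13786 of them with a gene symbol, and the other probes were compared with it for each named gene. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean for each group, all 16 arrays in the same fit, 12 residual degrees of freedom, two-sided) with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from this fit, and differences are given as log2 difference ± standard error (SE), with group means ± standard deviation (SD). The 5 contrasts were sh-SIRT1 against sh-Control in vehicle and under RA, RA against vehicle in each line, and the difference between the 2 RA effects. Where a gene was not well above background on any array of a group, only a lower bound of the fold is given ("at least"), computed against the lowest signal well above background on each array of that group or the probe's own signal, whichever was higher. This bound does not exist for a difference of RA responses or where both groups lay at background. With sh-Control RA array 1 alone, limma takes the spread from the other groups and the single array is assumed to vary like them.

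An RA response score was the mean log2 of RA-induced genes minus that of RA-repressed genes, with both sets called from the mean of the 2 RA contrasts (adjusted p under 0.05 and at least 1 log2 unit), and its differences were tested by exact two-sided permutation of the shRNA labels within treatments. In each alternative fit these sets were called anew unless stated. The 17 gene lists covered pluripotency, retinoid metabolism and receptors, Hox genes, Hox cofactors and Cdx genes, primitive endoderm, neuroectoderm, primitive streak and mesoderm, trophectoderm, germ line and meiosis, the 2-cell-like state, p53 targets, sirtuins and NAD synthesis, cholesterol synthesis, imprinted genes, mitosis and cell division, interferon response, and fibroblast markers for feeder cells. No gene belongs to more than 1 list. The numbers of list members well above background in all vehicle arrays were, in this order, 26, 20, 10, 8, 18, 16, 12, 12, 19, 6, 22, 14, 24, 22, 26, 13 and 14. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 85 tests, and again with an estimated correlation, under which none of the 42 calls held. The genes named in each contrast were the 8 with the largest rise and the 8 with the largest fall among those past the threshold with a symbol and without overlap of the groups (no such condition for the difference of RA effects), up to 4 members of each list, and Sirt1, Crabp2, Cyp26a1, Rarb, Pou5f1 and Nanog in all. Some genes that the rule names are not reported here. Groups, contrasts, filter, lists, this rule and the alternatives were fixed before the data were examined, except for 4 alternatives noted in the closing section.

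Tested on simulated data in which 200 of 18282 genes were changed, the fit recovered 30, 70, 92 and 98% of log2 changes of 0.5, 1, 2 and 3 in the vehicle contrast with 9 false calls. The same shares were 28, 64, 88 and 96% with 10 false calls for RA in sh-Control cells, and 46, 88, 96 and 98% with 12 false calls for the hairpins under RA. The simulated noise was independent between genes and between arrays, unlike the arrays here, which deviated together across lines. The false calls therefore do not measure error under such dependence. The number of arrays limits the precision.

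The arrays lay on 4 slides, each with arrays of 3 or 4 groups. Slide 4 held array 1 as its only sh-Control RA array. Values within slide 4 and against that array alone are thus not separate evidence. Slide was used as a fixed block, as a random block, and for differences within each slide that held the groups compared. Where lost calls are counted over alternatives, these differences within slides are included, although they carry no test and cannot lose a call. Replicate numbers of the labels were checked for pairing by the correlation over genes of deviations from the group means. Arrays of the same number in the 2 lines deviated together, with correlations of 0.363 to 0.513 in 3 vehicle pairs and 0.431 to 0.541 in 4 RA pairs, whereas vehicle and RA arrays of the same number did not (-0.0681 to -0.0287 in sh-Control, -0.211 to 0.219 in sh-SIRT1). Arrays of different numbers in the 2 lines ranged from -0.502 to 0.329 in vehicle and from -0.622 to 0.519 under RA, where sh-Control arrays 3 and 4 correlated more with other numbers than with their own. Each same-numbered pair lay above 0.1, and the numbers were used as pairing arrays across lines within a treatment. This is an assumption, since arrays of different numbers reached 0.329 in vehicle and 0.519 under RA. Under RA, sh-Control arrays 1 and 2 also correlated with sh-SIRT1 arrays 2 and 1 (0.381 and 0.316). With the number as a block within treatment, differences under RA leave out sh-SIRT1 RA arrays 5 and 6, which have no partner. The other alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes detected on all arrays, no filter or a stricter filter on dim probes, keeping marked spots, the series matrix, a fit on only the groups compared, a trended robust prior, RA replicates 1 to 3 only, all probes, a minimum of 1 log2 unit, and leaving out each array in turn.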

Results

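RNA of mouse E14 embryonic stem cells was hybridised to 16 whole-genome expression arrays. The cells expressed a control hairpin or a hairpin against Sirt1 and were kept for 2 days with vehicle or 20 nM RA, a vitamin A derivative that drives stem cells to differentiate. There were 3 arrays each of sh-Control and sh-SIRT1 cells in vehicle, 4 of sh-Control cells under RA and 6 of sh-SIRT1 cells under RA. On each array 60.3 to 68.6% of the probes were well above background, the 75th percentile of the processed intensity lay between 684 and 1155, and 0 to 4 spots were saturated. The title of the series states the question: whether loss of SIRT1 strengthens the response of these cells to RA.

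The targeted gene followed the labels. Sirt1 was at 3.66 ± 0.17 (SD, n = 3) in sh-Control and 1.85 ± 0.03 (n = 3) in sh-SIRT1 cells in vehicle, and at 3.36 ± 0.08 (n = 4) and 1.18 ± 0.26 (n = 6) under RA, in log2 units above the 75th percentile of the array. It fell by 1.81 ± 0.15 (SE, limma adjusted p = 4.05e-05, 3.5-fold) with the Sirt1 hairpin in vehicle and by 2.18 ± 0.12 (adjusted p = 2.48e-07, 4.53-fold) under RA, the latter by 2.39 within slide 2. The probe lies on chromosome 10 from 62855795 to 62855854 (build mm7), and a second probe at 62838289 to 62838348 gave differences of -1.85 and -2.62. RA lowered Sirt1 by a further log2 difference of -0.67 ± 0.13 in sh-SIRT1 cells (adjusted p = 6.45e-04), and the difference of -0.30 ± 0.14 in sh-Control cells did not pass (adjusted p = 0.105). The difference between these RA effects, -0.37 ± 0.20, did not pass either (adjusted p = 0.307).

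**Figure D1:**
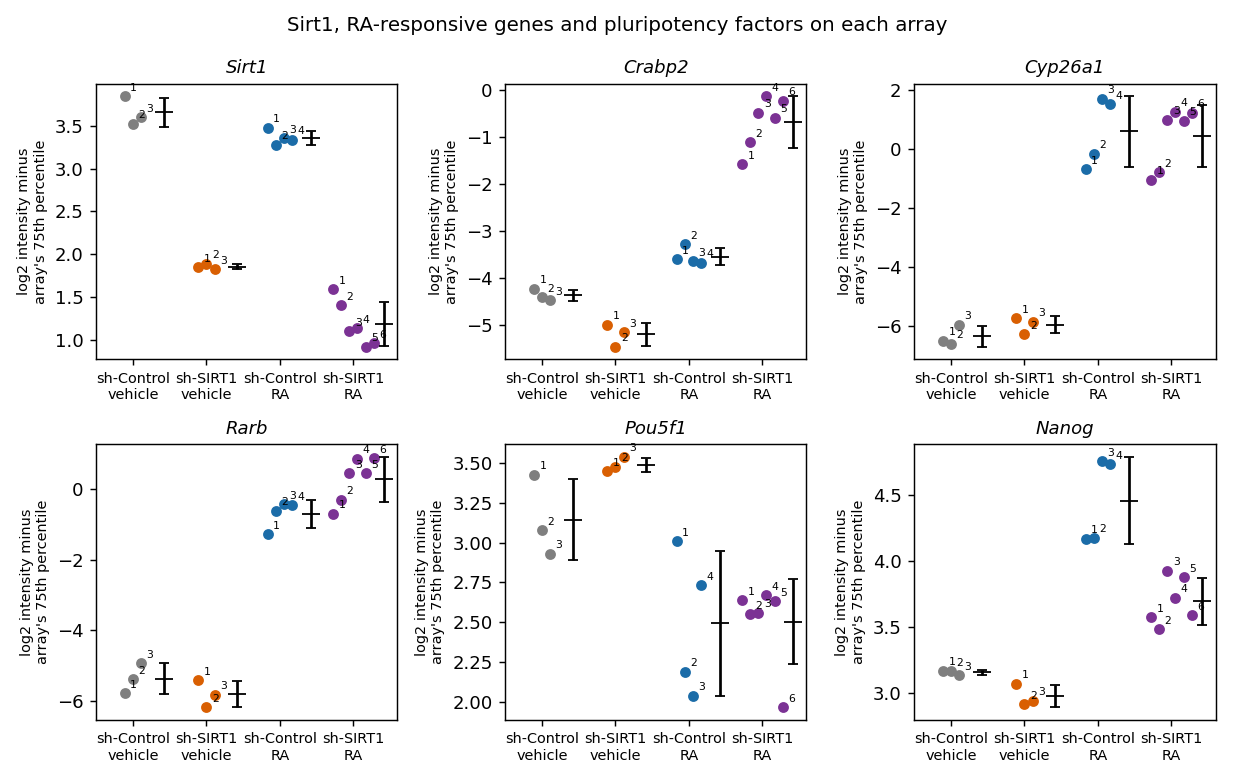
Log2 expression relative to each array's 75th percentile for Sirt1, the RA-responsive genes Crabp2, Cyp26a1 and Rarb, and the pluripotency genes Pou5f1 and Nanog in the 4 groups, with arrays as points and mean ± SD as lines with bars. Sirt1 lay at 1.85 and 1.18 on average in sh-SIRT1 cells against 3.66 and 3.36 in sh-Control cells, and Crabp2 under RA at -0.68 against -3.55.

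In vehicle, the comparison asks what the Sirt1 hairpin changed before any RA was given. The imprinted gene Grb10, an adaptor that restrains insulin and growth factor signalling, fell by 3.25 ± 0.34 (adjusted p = 1.26e-04, 9.51-fold, probe on chromosome 11 from 11882970 to 11883029). The trophoblast gene Plet1 fell by 3.19 ± 0.41 (adjusted p = 4.12e-04, 9.11-fold) and Rusc2 by 2.99 ± 0.31. The ribosomal protein gene Rpl39l fell by 2.94 ± 0.50 and the X-linked homeobox gene Rhox5 by 2.76 ± 0.77. The Rhox5 call was lost in 12 of 33 alternatives, and its smallest difference over these was -0.117. Sytl3, a vesicle trafficking gene, was at least 4.21-fold lower (adjusted p = 1.70e-04) and the germ cell gene Fkbp6 at least 5.93-fold lower (adjusted p = 7.99e-04), with no sh-SIRT1 vehicle array well above background. Among genes that rose, the transcription factor gene Bhlhe22 was at least 5.62-fold higher (adjusted p = 5.08e-05), Nap1l5, another imprinted gene, at least 1.18-fold higher, and Ccn2, a secreted matrix protein, rose by 1.85 ± 0.29 (3.61-fold, adjusted p = 0.00183). Slc39a8, a metal transporter, rose by 2.47 ± 0.59, and Vmo1 by 1.87 ± 0.35, both well above background on 1 of 3 sh-Control vehicle arrays.

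Of 24 germ line and meiosis genes 5 fell and 1 rose (10 and 2 when adjusted over the list alone), among them the meiotic cohesin Smc1b, down by 2.08 ± 0.44, Tex101, down by 1.94 ± 0.48, and the piRNA pathway genes Rnf17 and Mael, at -1.33 ± 0.21 and -1.04 ± 0.22. The median of this list was -0.41 (camera adjusted p = 0.0048; adjusted p = 0.403 with an estimated correlation; -0.52 to -0.27 without single arrays). Of 23 retinoid genes 2 fell (4 adjusted over the list alone), the plasma retinol carrier Rbp4, down by 1.87 ± 0.28, and the retinol receptor Stra6, down by 0.73 ± 0.19, with a list median of -0.30 (adjusted p = 0.0152; adjusted p = 0.176 with an estimated correlation). Within slides 1 and 3 this median was -0.30 and -0.29. The RA targets Crabp2 (-0.83 ± 0.30) and Rarb (-0.44 ± 0.39) did not pass, and Cyp26a1 was not well above background on any vehicle array. Of 11 Hox cofactors and Cdx genes 2 rose (3 adjusted over the list alone), Meis1 by at least 1.88-fold and Tshz1 by 1.74 ± 0.47, although another Tshz1 probe had the opposite sign, and the list median was 0.21 (adjusted p = 0.0385; adjusted p = 0.300 with an estimated correlation; 0.18 to 0.32 without single arrays). Of 30 Hox genes 3 rose, Hoxd12 by at least 1.36-fold, Hoxa7 by 1.09 ± 0.31 and Hoxb9 by 0.81 ± 0.17. This list did not pass (median 0.12, adjusted p = 0.442). The calls of Hoxa7, Stra6 and Tex101 were lost in 13, 9 and 8 of 33 alternatives, and that of Meis1 in 8 of 32.

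None of the 26 primitive endoderm genes changed singly in this limma fit, and their median was -0.49 (adjusted p = 0.0467; adjusted p = 0.719 with an estimated correlation). The list mean on single vehicle arrays, picked out afterwards, was -2.29, -2.29 and -2.42 in sh-Control and -3.13, -2.83 and -2.79 in sh-SIRT1 cells. The fit estimates its spread from all groups, and among the sh-Control RA arrays this mean ran from -1.17 to 1.58. The lack of single calls and the loss with an estimated correlation therefore do not show that these genes were unchanged in vehicle. With replicates paired as a block within treatment, the primitive endoderm and Hox cofactor lists no longer passed (adjusted p = 0.0584 and 0.0737). No pluripotency gene of 26 passed in limma (median -0.15, adjusted p = 0.240), and Pou5f1 (0.34 ± 0.24) and Nanog (-0.18 ± 0.16) did not pass. Of 18 interferon response genes 3 fell, Oas1a by 2.35 ± 0.42, Oas2 by 1.34 ± 0.23 and Parp14 by 0.57 ± 0.17, without a call for the list (median -0.27, adjusted p = 0.0728). Parp14 lost its call in 17 of 33 alternatives. Of 19 fibroblast markers, genes of feeder cells, 3 fell (5 adjusted over the list alone), Thy1 by 2.48 ± 0.56, Col5a1 by 0.87 ± 0.17 and Fbln1 by 0.73 ± 0.11 (median -0.34, adjusted p = 0.0754). Of the 19, 14 were well above background in all vehicle arrays, and with genes below background at their bound the median was -0.12. Among 14 sirtuin and NAD synthesis genes Sirt4 (0.62 ± 0.10), Nmnat1 (0.62 ± 0.18) and Qprt (0.42 ± 0.11) rose and Sirt1 fell, with no call for the list (median -0.10, adjusted p = 0.91). Qprt lost its call with replicates as a block within treatment (adjusted p = 0.0552). Of 17 mesoderm genes 2 rose and 1 fell, Kdr by 2.32 ± 0.42. Of 14 trophectoderm genes 1 rose and 3 fell, and of 18 neuroectoderm genes 1 rose. These 3 lists did not pass (adjusted p = 0.861, 0.147 and 0.884). The p53 target, cholesterol synthesis, 2-cell-like and mitosis lists had 1, 1, 0 and 0 changed members and did not pass (adjusted p = 0.991, 0.920, 0.141 and 0.720).

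In all, 1576 of 18282 genes passed (806 higher, 770 lower in sh-SIRT1 cells), of which 468 differed by at least 1 log2 unit, 117 higher and 351 lower. The hairpin and the history of each line cannot be told apart in this design, which holds for each sh-SIRT1 comparison given here. The count was 3516 with replicates as a block within treatment, 975 with slide as a fixed block and 270 after normexp correction. It was 820 and 739 without sh-Control vehicle arrays 2 and 3, and 975, 916 and 972 without sh-SIRT1 vehicle arrays 1, 2 and 3.

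Genes placed on chromosome 8 lay higher in sh-SIRT1 cells as a group. Over its 962 genes the median difference was 0.36 in vehicle and 0.26 under RA, a 1.28-fold and a 1.19-fold difference, and 79.4% and 75.1% of them were higher. They made up 28.8% of all genes called higher in vehicle and 19.2% under RA, against 5.26% of the genes tested. Medians of the other autosomes and of chromosome X lay between -0.05 and 0.09 in vehicle and between -0.08 and 0.00 under RA. Without chromosome 8, 1244 genes passed in vehicle and 3328 under RA.

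**Figure D2:**
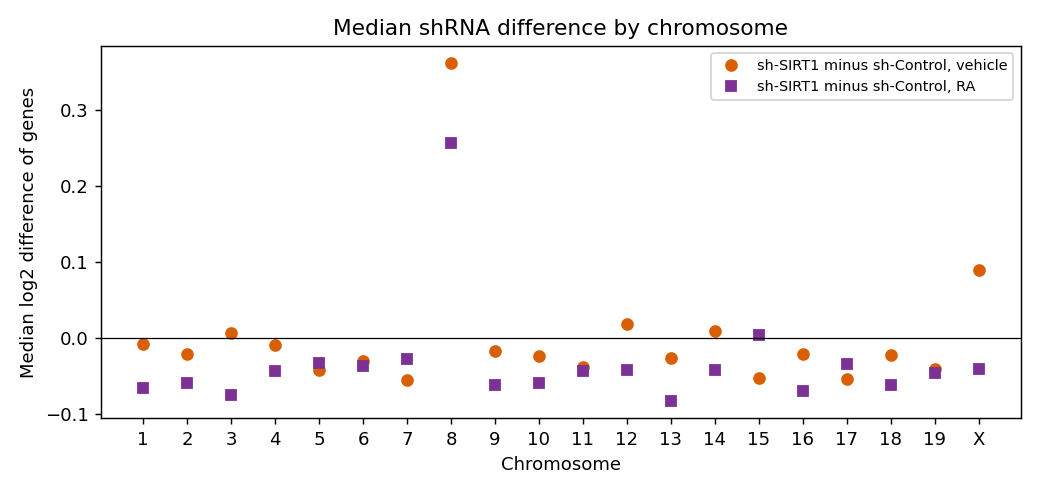
Median log2 difference between sh-SIRT1 and sh-Control cells over the genes of each chromosome, in vehicle and under RA. Chromosome 8 lay at 0.36 and 0.26, and the next highest value was 0.09, for chromosome X in vehicle.

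RA was compared with vehicle in sh-Control cells, in which Sirt1 was not targeted. Most of these RA arrays differed from the vehicle arrays in Y-linked genes, as given below. The genes of a 2-cell-like state, transcribed in the early embryo and in rare stem cells, had some of the largest rises: Zscan4c by 9.37 ± 0.52 (adjusted p = 1.85e-08, probe on chromosome 7 from 9713271 to 9713330), Tcstv1 by 8.55 ± 0.57, Tcstv3 by 8.32 ± 0.53 and Usp17la by 7.97 ± 0.44. Of this list 10 of 11 genes rose. The 2-cell-like median was 5.47 (adjusted p = 3.27e-09; adjusted p = 0.125 with an estimated correlation). Pramel37, well above background on 1 of 3 vehicle arrays, rose by 8.80 ± 0.66. Stra8, the RA-induced gatekeeper of meiosis, rose by 8.07 ± 0.60 (adjusted p = 2.29e-07), and Cyp26a1, the enzyme that degrades RA, was at least 68.3-fold higher (adjusted p = 1.87e-06). The RA receptor gene Rarb (well above background on 1 of 3 vehicle arrays) rose by 4.69 ± 0.37, the retinaldehyde reductase gene Dhrs3 by 3.26 ± 0.50 and Crabp2, which carries RA to its receptors, by 0.83 ± 0.28 (adjusted p = 0.0251). Of the 23 retinoid genes 14 rose and 5 fell. The retinoid median was 1.13 (adjusted p = 6.97e-04; adjusted p = 0.122 with an estimated correlation).

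Among 30 Hox genes, which pattern the body axis, 23 rose and 0 fell: Hoxb2 was at least 115-fold, Hoxb1 at least 20.2-fold, Hoxc9 at least 14.7-fold and Hoxb5 at least 11.4-fold higher. The list median was 2.92, or 1.98 with genes below background at their bound (adjusted p = 7.69e-12; adjusted p = 0.125 with an estimated correlation). Of the 30, 10 were well above background in all vehicle arrays. Of 11 Hox cofactors and Cdx genes 10 rose and 1 fell, with Cdx2 at least 10.8-fold higher, Tshz1 up by 3.75 ± 0.44 and Meis2 by 3.14 ± 0.53. The Hox cofactor median was 1.73 (adjusted p = 3.00e-05; adjusted p = 0.122 with an estimated correlation). Within slides 1 and 4 the Hox median was 2.01 and 4.16.

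Lineage genes rose along with these. Of 26 primitive endoderm genes 15 rose, among them Foxa2 by 4.72 ± 0.45, Col4a1 by 4.25 ± 0.76, Gata6 by 4.07 ± 0.52 (of its other probes, 1 of 2 had the same sign) and Srgn by 4.95 ± 1.20. The primitive endoderm median was 2.40 (adjusted p = 1.74e-05; adjusted p = 0.434 with an estimated correlation). Within slides 1 and 4 this median was 1.02 and 4.05, and 18 of the 26 were well above background in all vehicle arrays. Of 14 trophectoderm genes 9 rose and 2 fell, with Gata3 at least 16.6-fold and Hand1 at least 6.86-fold higher and Esx1 up by 3.35 ± 0.37. The trophectoderm median was 1.86 (adjusted p = 0.0014; adjusted p = 0.255 with an estimated correlation). Of 17 mesoderm genes 7 rose and 2 fell, with Gsc (2 of 3 vehicle arrays well above background) up by 3.81 ± 0.77, Foxc2 at least 2.56-fold higher and Eomes up by 2.47 ± 0.16. The mesoderm median was 0.61 (adjusted p = 0.0048; adjusted p = 0.125 with an estimated correlation). Of 24 germ line genes 15 rose, including Dazl by 2.81 ± 0.17, Taf7l by 2.62 ± 0.31 and Brdt by at least 3.20-fold. The germ line median was 0.92 (adjusted p = 1.02e-07; adjusted p = 0.157 with an estimated correlation). Neuroectoderm genes were split, 4 up and 4 down of 18 (median -0.23, although camera gave the direction as up, adjusted p = 0.908). Otx2 fell by 4.00 ± 0.85 and Neurod1 by 3.68 ± 0.84, the latter well above background on 2 of 4 RA arrays. Fibroblast markers moved with these groups: 9 of 19 rose and 1 fell (10 and 1 adjusted over the list alone), with Col1a1 up by 3.33 ± 0.54 and Col1a2 by 2.61 ± 0.66. The fibroblast median was 1.504, or 1.09 with genes below background at their bound (camera adjusted p = 7.91e-04, or 0.394 with an estimated correlation).

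Pluripotency genes went both ways in sh-Control cells, 11 down and 4 up of 26 (median -0.30, adjusted p = 0.401). Nr0b1 fell by 1.56 ± 0.18, Gdf3 by 1.43 ± 0.25, Utf1 by 1.29 ± 0.22 and Pou5f1, the core factor of the stem cell state, by 0.65 ± 0.22 (adjusted p = 0.0266). Nanog rose by 1.30 ± 0.15 (adjusted p = 1.55e-05). For Pou5f1 the fall rested on arrays 2 to 4, since the difference was -0.13 with array 1 alone. Within slide 4, which holds array 1 as its only sh-Control RA array, the difference was 0.08. Of 26 mitosis genes 13 fell and 1 rose, with Cenpf down by 0.49 ± 0.09 and Plk1 by 0.48 ± 0.08. The mitosis median was -0.27 (adjusted p = 0.0216; adjusted p = 0.575 with an estimated correlation). Of 24 cholesterol synthesis genes 12 rose and 1 fell, with Hsd17b7 up by 0.79 ± 0.10 and Cyp51 by 0.72 ± 0.13. The cholesterol synthesis median was 0.36 (adjusted p = 7.91e-04; adjusted p = 0.394 with an estimated correlation). The p53 target (4 up, 7 down of 22), interferon (5 up, 7 down of 18; 6 up adjusted over the list alone), sirtuin (1 up, 5 down of 14) and imprinted gene (7 up, 9 down of 24) lists did not pass (adjusted p = 0.861, 0.908, 0.35 and 0.72). Among their members the p53 target Sesn1 rose by 1.42 ± 0.13 and Bbc3 fell by 1.27 ± 0.12. The viral RNA sensor Ddx58 fell by 3.85 ± 0.32, while Oasl2 was at least 6.73-fold and Usp18 at least 1.9-fold higher. Naprt fell by 1.63 ± 0.16 and Sirt5 by 0.94 ± 0.11. The imprinted genes Igf2 and Dlk1 rose by 4.45 ± 0.95 and 2.58 ± 0.50. Other large falls were those of Egr1 (-3.91 ± 0.46), Grhl2 (-3.82 ± 0.38) and the potassium channel gene Kcnh8 (at least 7.13-fold lower).

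In total 8562 genes passed in sh-Control cells (3594 higher, 4968 lower), and 2882 of them differed by at least 1 log2 unit, 1964 higher and 918 lower. The median of all genes was -0.14 in sh-Control and -0.13 in sh-SIRT1 cells, and -0.03 and -0.01 after normexp correction, so that small falls are to be read against this shift. The sh-Control RA group was not uniform: on its arrays 2, 3 and 4 the Y-linked gene Ddx3y lay at -6.91, -8.01 and -8.12, against 0.23 on array 1 and 0.33 to 1.60 on the vehicle arrays. Its RA difference (-6.48 ± 1.42) was -0.54 with array 1 alone (adjusted p = 0.306), and that of the imprinted gene Nnat (-3.46 ± 1.05) was 0.91. Both genes were not well above background on arrays 2 to 4, so these fitted differences are not sizes. The sh-Control vehicle arrays did not share these low values. A difference in the cells behind arrays 2 to 4 therefore cannot be told apart from RA on them, which holds for each comparison that uses these arrays. Crabp2, Gsc and Otx2 had differences of 0.78, 2.88 and -3.07 with array 1 alone and lost their calls (adjusted p = 0.206, 0.0722 and 0.0534) in that fit, in which the group is a single array and 7083 genes passed.

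**Figure D3:**
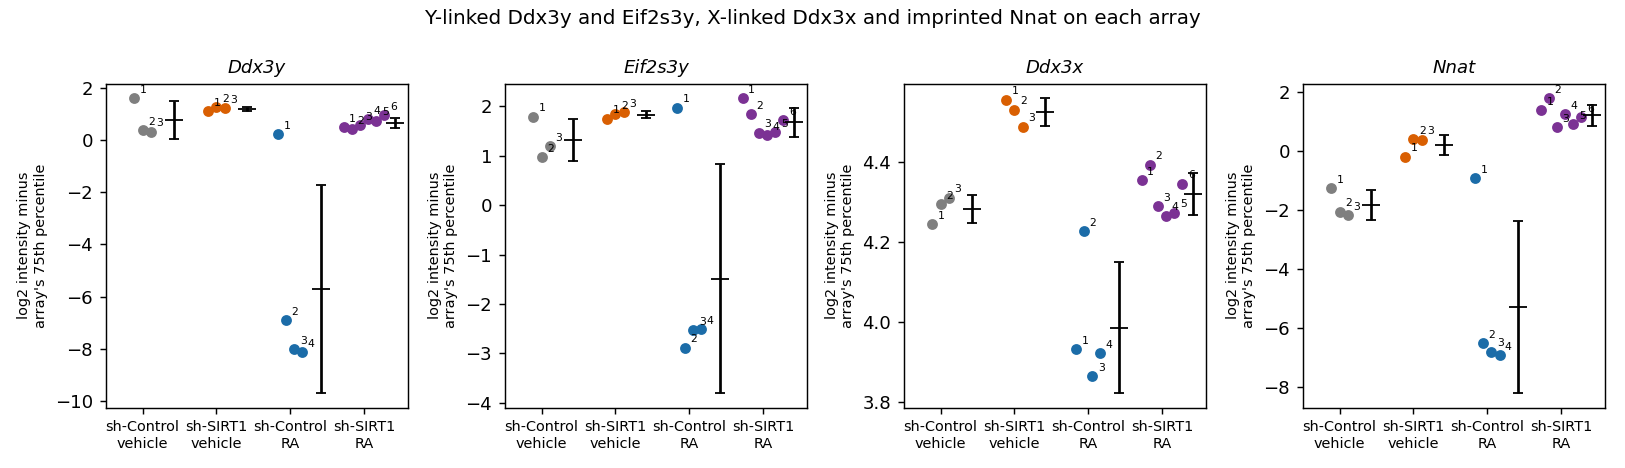
Log2 expression of the Y-linked genes Ddx3y and Eif2s3y, the X-linked Ddx3x and the imprinted gene Nnat on each of the 16 arrays. On sh-Control RA arrays 2 to 4 Ddx3y lay at -6.91 to -8.12, and Ddx3x differed over all arrays by 0.69.

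RA in sh-SIRT1 cells moved most of the same lists. Hoxb2, well above background on 1 of 3 vehicle arrays as was Rarb, rose by 8.96 ± 0.36 (adjusted p = 7.83e-10), Hoxc9 was at least 186-fold, Hoxb1 at least 80.1-fold and Hoxb5 at least 63.6-fold higher. Of 30 Hox genes 26 rose and 1 fell (27 and 1 adjusted over the list alone; median 3.62, or 3.34 with genes below background at their bound, adjusted p = 3.62e-14; adjusted p = 0.122 with an estimated correlation). Crabp2 (2 of 3 vehicle arrays well above background) rose by 4.52 ± 0.26 (adjusted p = 1.15e-08), Rarb by 6.09 ± 0.34, Dhrs3 by 6.07 ± 0.46, Stra8 by 8.37 ± 0.56, and Cyp26a1 was at least 70.8-fold higher. Of 23 retinoid genes 14 rose and 4 fell. The retinoid median was 1.39 (adjusted p = 5.72e-05; adjusted p = 0.122 with an estimated correlation). Zscan4c rose by 7.91 ± 0.48, Tcstv1 by 6.80 ± 0.53 and Usp17la by 6.24 ± 0.41. Of 11 genes of the 2-cell-like list 10 rose. The 2-cell-like median was 4.78 (adjusted p = 6.98e-07; adjusted p = 0.160 with an estimated correlation). Zfp503 was at least 60.1-fold higher.

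Among the lineage lists, 19 of 26 primitive endoderm genes rose (Foxa2, well above background on 2 of 3 vehicle arrays, by 5.41 ± 0.41, Col4a2 by 4.98 ± 0.76; median 2.63, adjusted p = 6.98e-07; adjusted p = 0.394 with an estimated correlation). Trophectoderm genes rose in 10 cases of 14 and 1 fell (Gata3 by 4.85 ± 0.38, Krt7 by 4.17 ± 0.57, Gata2 by 3.05 ± 0.20; median 2.19, adjusted p = 5.25e-05; adjusted p = 0.160 with an estimated correlation). Of 17 mesoderm genes 9 rose and 3 fell, with Meox1, a gene of the somites, up by 5.57 ± 0.54 and Foxc1 at least 12-fold higher. The mesoderm median was 0.77 (adjusted p = 0.00152; adjusted p = 0.122 with an estimated correlation; 0.49 to 0.97 without single arrays). Germ line genes rose in 18 of 24 cases (median 1.20, adjusted p = 1.48e-07; adjusted p = 0.158 with an estimated correlation), Hox cofactors and Cdx genes in 10 of 11 with 1 fall (Cdx1 by 3.51 ± 0.26; median 2.59, adjusted p = 3.24e-05; adjusted p = 0.122 with an estimated correlation). Of the fibroblast markers 14 of 19 rose (Col1a1 by 4.01 ± 0.50, Col1a2 by 3.86 ± 0.61; median 1.95, adjusted p = 8.11e-06; adjusted p = 0.275 with an estimated correlation). Neuroectoderm genes again went both ways (7 up, 4 down of 18; adjusted p = 0.241), with Zic1 up by 2.48 ± 0.56, Fabp7 at least 3.89-fold higher and Otx2 (4 of 6 RA arrays well above background) down by 4.45 ± 0.79.

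Pluripotency genes fell in 14 of 26 cases and rose in 4 (median -0.70, adjusted p = 0.0728), with Nr0b1 down by 2.00 ± 0.17, Nr5a2 by 1.86 ± 0.17, Gdf3 by 1.64 ± 0.23, Utf1 by 1.46 ± 0.20 and Pou5f1 by 0.98 ± 0.21 (adjusted p = 9.38e-04). Nanog rose by 0.72 ± 0.14 (adjusted p = 6.39e-04). Mitosis genes fell in 23 of 26 cases, Kif11, a spindle motor, by 0.86 ± 0.10, Nusap1 by 0.78 ± 0.10 and Cenpf by 0.77 ± 0.08. The mitosis median was -0.46 (adjusted p = 5.01e-05; adjusted p = 0.370 with an estimated correlation). Of 14 sirtuin and NAD synthesis genes 7 fell, including Naprt by 1.80 ± 0.14, Sirt5 by 0.88 ± 0.10 and Nampt by 0.77 ± 0.12. The sirtuin list median was -0.33 (camera adjusted p = 0.0493, or 0.160 with an estimated correlation), a call lost in 19 of 33 alternatives. Cholesterol synthesis genes rose in 13 of 24 cases and 1 fell (Cyp51 by 0.77 ± 0.12; median 0.34, adjusted p = 0.00253; adjusted p = 0.404 with an estimated correlation). The p53 target, interferon and imprinted gene lists did not pass (adjusted p = 0.657, 0.681 and 0.215). Trp53 fell by 1.07 ± 0.12, Bbc3 by 1.00 ± 0.11 and Ddx58 by 3.64 ± 0.29. Igf2 rose by 5.41 ± 0.88, Dlk1 by 4.25 ± 0.46 and Peg12 by 2.78 ± 0.18. Further falls were those of Enox1 (-4.71 ± 0.22), Glod5 (-4.24 ± 0.58), Grhl2 (-4.09 ± 0.35) and Myb (-3.82 ± 0.14).

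In sh-SIRT1 cells 10644 genes passed (4199 higher, 6445 lower), with 3523 of at least 1 log2 unit, 2453 higher and 1070 lower. Between the lines 2864 genes were called higher under RA in both and 4062 lower in both, against 825 and 1751 for independent lists, and 30 and 47 in opposite directions. No array was shared between these comparisons, and across genes, which are not independent replicates, the RA differences correlated with r = 0.87.

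Under RA, the comparison of the lines asks whether cells with the Sirt1 hairpin differ after treatment. Crabp2 rose by 2.86 ± 0.23 (adjusted p = 8.36e-06, 7.28-fold, probe on chromosome 3 from 88062561 to 88062620), the somite gene Meox1 by 3.52 ± 0.50 (adjusted p = 3.84e-04), Hoxc9 by 3.45 ± 0.65, Tshz1 by 2.67 ± 0.37, and Nap1l5 was at least 3.55-fold and Tll1 at least 3.66-fold higher. Grb10 fell by 3.61 ± 0.27 (adjusted p = 4.84e-06, 12.2-fold), Rhox5 by 3.97 ± 0.61, Fkbp6 (5 of 6 sh-SIRT1 arrays well above background) by 3.62 ± 0.38, Cpsf4l by 3.06 ± 0.35 and Rpl39l by 2.73 ± 0.40, and Herc5 and Wif1 were at least 3.2-fold and 2-fold lower. Nnat and Ddx3y, well above background on 1 of 4 sh-Control RA arrays, passed with fitted differences of 6.50 ± 0.89 and 6.37 ± 1.20, which are not sizes and which against sh-Control RA array 1 alone were 2.14 (adjusted p = 0.00659) and 0.44 (adjusted p = 0.481). The RA target Cyp26a1 (-0.16 ± 0.55) and the stem cell factor Pou5f1 (0.01 ± 0.19) did not pass.

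Of 30 Hox genes 20 rose and 0 fell (21 adjusted over the list alone), among them Hoxc6 by 2.87 ± 0.69, Hoxd4 by 2.35 ± 0.31 and Hoxa5 by 2.34 ± 0.40. Of the 4 sh-Control RA arrays, Hoxc6 was well above background on 2 and Hoxd4 on 1. The list median was 1.21 (adjusted p = 6.67e-11; adjusted p = 0.146 with an estimated correlation). It was 1.79, 1.27 and 0.64 within slides 1, 2 and 4 and 0.66 against sh-Control RA array 1 alone (adjusted p = 9.28e-06). Of the 11 Hox cofactors and Cdx genes 6 rose (7 adjusted over the list alone), Meis2 by 2.31 ± 0.45, Meis1 by 2.22 ± 0.44 and Cdx2 by 1.40 ± 0.47 (median 0.87, adjusted p = 5.98e-04; adjusted p = 0.125 with an estimated correlation), with a median of 0.37 against array 1 alone. Among 23 retinoid genes 3 rose, including Dhrs3 by 1.47 ± 0.42 and Rarb by 0.97 ± 0.31, and 1 fell, the RA-synthesising enzyme gene Aldh1a2 (-0.96 ± 0.22), without a call for the list (median -0.05 although camera gave the direction as up, adjusted p = 0.589).

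Of 26 pluripotency genes 11 fell and 0 rose (13 adjusted over the list alone), with Tdgf1 down by 1.06 ± 0.16, Fbxo15 by 1.01 ± 0.20, Sox2 by 0.95 ± 0.16 and Nanog by 0.76 ± 0.13. The pluripotency median was -0.43 (adjusted p = 4.79e-05; adjusted p = 0.122 with an estimated correlation). Within slides 1, 2 and 4 the median was -0.56, -0.41 and -0.51. Of 26 mitosis genes 13 fell (17 adjusted over the list alone), Nusap1 by 0.54 ± 0.09, Mad2l1 by 0.42 ± 0.08, Kif11 by 0.40 ± 0.09 and Cenpf by 0.38 ± 0.08 (median -0.26, adjusted p = 1.80e-06; adjusted p = 0.279 with an estimated correlation), and the median within slide 4 was -0.09. The cell cycle inhibitor Cdkn1a rose by 0.71 ± 0.11, while Trp53 and Gadd45a fell by 0.54 ± 0.11 and 0.95 ± 0.18, and the p53 target list did not pass (adjusted p = 0.884). Germ line genes fell in 10 of 24 cases and rose in 3, with Smc1b down by 1.92 ± 0.35, Rnf17 by 1.35 ± 0.16 and Dppa1 up by 2.31 ± 0.51. The germ line median was -0.42 (adjusted p = 0.0488; adjusted p = 0.559 with an estimated correlation). Of 24 imprinted genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with Peg10 up by 2.10 ± 0.46 and Dlk1 by 1.98 ± 0.42. Peg10 and Dppa1 were well above background on 3 of 4 sh-Control RA arrays. The imprinted gene median was 0.50 (adjusted p = 0.0312; adjusted p = 0.447 with an estimated correlation), and 0.25 to 0.61 without single arrays. Against array 1 alone neither of these lists passed (adjusted p = 0.184 and 0.578).

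The neuroectoderm genes Sox1 (1.59 ± 0.31), Zic1 (1.52 ± 0.51) and Nes (1.25 ± 0.18) rose, as did the mesoderm genes Foxc1 (2.05 ± 0.49) and Foxc2 (1.12 ± 0.14) and the trophectoderm genes Gata3 (1.59 ± 0.34) and Gata2 (0.90 ± 0.18), whereas Wnt3a fell by 1.43 ± 0.35. These lists had 5, 6 and 3 rises and 1, 1 and 2 falls and did not pass (adjusted p = 0.089, 0.0663 and 0.354). No primitive endoderm gene passed in limma (median -0.13, adjusted p = 0.879), and 2 of 19 fibroblast markers rose and 1 fell (median 0.49, adjusted p = 0.089). The 2-cell-like genes Usp17la (-1.18 ± 0.38) and Arg2 (-0.77 ± 0.26) and the interferon genes Oas1a (-1.10 ± 0.33) and Parp14 (-0.94 ± 0.13) fell without a call for their lists (adjusted p = 0.089 and 0.39). The sirtuin and cholesterol lists had 1 and 2 rises and 4 and 2 falls (adjusted p = 0.183 and 0.698).

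In this comparison 3706 genes passed (1571 higher, 2135 lower), 623 of them by at least 1 log2 unit, 327 higher and 296 lower. With sh-Control RA array 1 alone 2030 passed, with RA replicates 1 to 3 alone 563, and after normexp correction 1122. With array 1 alone, a group of 1, calls were lost for Rarb (1.55), Dhrs3 (1.76), Meis1 (1.86) and Hoxa5 (1.77), with adjusted p = 0.0896, 0.134, 0.0582 and 0.140, and for Hoxc6 (1.15), Nanog (-0.47) and Cdkn1a (0.36), with adjusted p = 0.127, 0.0768 and 0.158. Calls were lost there too for Trp53 (-0.22, adjusted p = 0.387), Wnt3a (-0.50), Sox1 (0.59), Dppa1 (0.33), Peg10 (1.00) and Kif11 (-0.11). The same held for Cdx2, Zic1, Foxc1, Gata2, Fbxo15, Rhox5, Smc1b, Dlk1, Nusap1, Mad2l1, Cenpf, Gadd45a, Usp17la, Arg2 and Oas1a. The differences of Rarb and Dhrs3 were larger in that fit than with all arrays, so a lost call there does not show that a difference went away. With replicates as a block within treatment Rarb, Aldh1a2, Cdx2 and Arg2 lost theirs (adjusted p = 0.0511, 0.0501, 0.0966 and 0.118). Over 33 alternatives the calls of Zic1, Cdx2, Rarb and Arg2 were lost in 21, 22, 18 and 17. Of the genes called in vehicle and under RA, 405 were higher in both and 302 lower in both, against 69.3 and 89.9 for independent lists. In opposite directions went 29 and 40 (r = 0.34 across genes, no shared arrays). Chromosome 8, higher as a group in both comparisons, held 232 of the 806 genes called higher in vehicle and 302 of the 1571 under RA. The overlap without chromosome 8 was not counted.

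The response to RA itself was compared between the lines, which is the question of the title. Crabp2 responded more in sh-SIRT1 cells, by a log2 difference of 3.70 ± 0.38 (adjusted p = 5.31e-04), with 2 of 3 sh-SIRT1 vehicle arrays well above background. So did Meox1 by 4.39 ± 0.80 (adjusted p = 0.0113), Dhrs3 by 2.82 ± 0.68 and the neural progenitor gene Nes by 1.31 ± 0.28. Hoxa5, Hoxd4 and Foxc2 also passed with a higher response (adjusted p = 0.0124, 0.0125 and 0.00307) and the Wnt inhibitor gene Wif1 with a lower (adjusted p = 0.0283), but no vehicle array of at least 1 line was well above background for them, so no size is given here. The bicarbonate transporter gene Slc4a7 had a lower response in sh-SIRT1 cells, by -3.17 ± 0.24 (adjusted p = 4.39e-05), being higher than sh-Control in vehicle and lower under RA. Others with a lower response were Sox18 (-1.69 ± 0.41) and Irx2 (-1.58 ± 0.27). The difference did not pass for Rarb (1.41 ± 0.50, adjusted p = 0.127), Nanog (-0.58 ± 0.21, adjusted p = 0.132), Pou5f1 (-0.33 ± 0.30, adjusted p = 0.585), Sox2 (-0.85 ± 0.25, adjusted p = 0.0754) or Tdgf1 (-0.91 ± 0.26, adjusted p = 0.0697).

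By lists, the Hox response was higher in sh-SIRT1 cells, with 4 of 30 genes up and 1 down (13 and 1 adjusted over the list alone). The Hox median was 1.10 (camera adjusted p = 3.14e-07, or 0.238 with an estimated correlation). Of the 30, only 10 were well above background in all vehicle arrays, so this median is not a size. The response of retinoid genes was higher too (3 of 23 up, 4 adjusted over the list alone). The retinoid median was 0.26 (camera adjusted p = 0.0064, or 0.157 with an estimated correlation). Fibroblast markers had a median of 0.68 (1 of 19 up; adjusted p = 9.57e-04; adjusted p = 0.394 with an estimated correlation). Pluripotency and mitosis genes had lower medians, -0.40 (no member of 26 passed in limma; adjusted p = 0.00885; adjusted p = 0.255 with an estimated correlation) and -0.25 (1 of 26 down, 7 adjusted over the list alone; adjusted p = 2.46e-04; adjusted p = 0.394 with an estimated correlation). The 2-cell-like list had a median of -1.32 (1 of 11 down; adjusted p = 0.00791; adjusted p = 0.404 with an estimated correlation), which was -2.20 to -0.93 without single arrays. Trophectoderm genes had a median of 0.25 (2 of 14 up; adjusted p = 0.0256; adjusted p = 0.394 with an estimated correlation), which was 0.07 to 0.53 without single arrays. Primitive endoderm (median 0.54, adjusted p = 0.0488; adjusted p = 0.719 with an estimated correlation) and imprinted genes (median 0.35, adjusted p = 0.0443; adjusted p = 0.471 with an estimated correlation) had no member that passed, and their medians were 0.25 to 1.08 and 0.30 to 0.48 without single arrays. The Hox cofactor, neuroectoderm, mesoderm, germ line and p53 target lists did not pass (adjusted p = 0.198, 0.112, 0.0728, 0.453 and 0.884). Nor did the sirtuin, cholesterol synthesis and interferon lists (adjusted p = 0.105, 0.879 and 0.402). Against sh-Control RA array 1 alone the primitive endoderm median was -1.29, and the trophectoderm, 2-cell-like, imprinted, mitosis and fibroblast lists did not pass (adjusted p = 0.320, 0.0537, 0.956, 0.103 and 0.126).

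**Figure D4:**
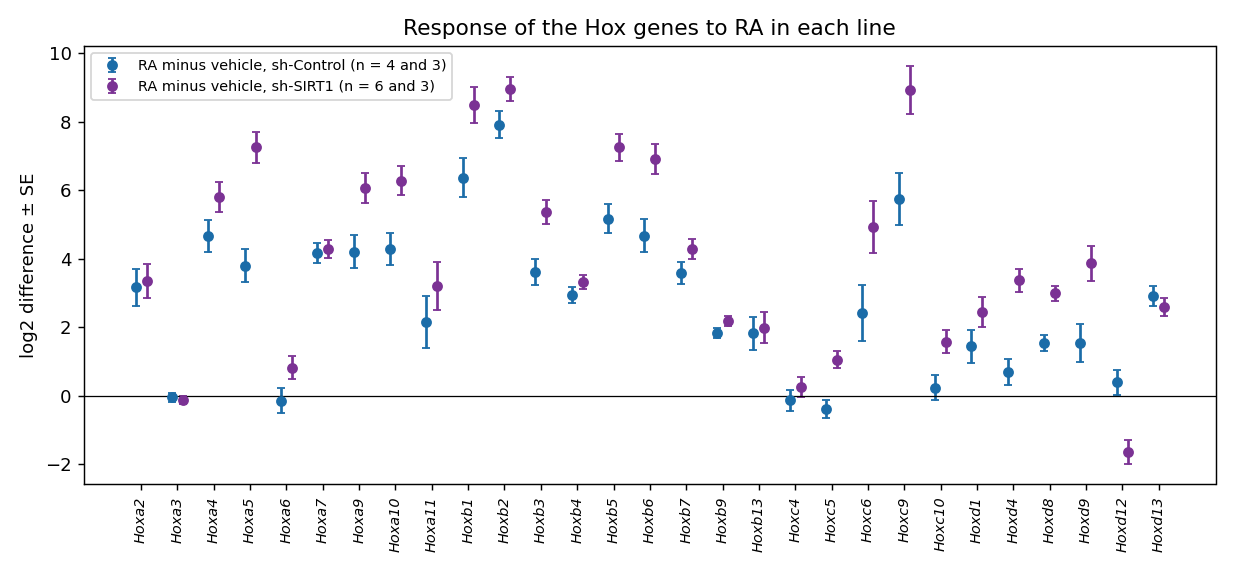
Log2 difference of RA minus vehicle ± SE for Hox genes in sh-Control and in sh-SIRT1 cells. The medians over all 30 genes of the list were 2.92 and 3.62, or 1.98 and 3.34 with genes below background at their bound.

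In all, 657 genes differed in their RA response (313 higher, 344 lower), 248 of them by at least 1 log2 unit, 194 higher and 54 lower. This count was 1656 with replicates as a block within treatment, 92 with slide as a fixed block, 22 after normexp correction, 199 with sh-Control RA array 1 alone and 12 with RA replicates 1 to 3. Without single arrays it ran from 204 to 1885. With array 1 alone Dhrs3 (3.101) and Meox1 (3.08) lost their calls (adjusted p = 0.119 and 0.0506), as did Nes (1.28), Sox18 (-0.98) and Hoxa5 (adjusted p = 0.0677, 0.307 and 0.146), and Crabp2 kept its call at 3.74 (adjusted p = 0.0125). Over 31 alternatives the calls of Dhrs3 and Sox18 were lost in 20 and 16.

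The RA response score, over 2257 induced and 910 repressed genes, put the size of the whole response in a single value. It was -3.09 ± 0.238 (SD, n = 3) in sh-Control and -3.16 ± 0.120 (n = 3) in sh-SIRT1 cells in vehicle, and 0.353 ± 0.208 (n = 4) and 0.6246 ± 0.0751 (n = 6) under RA, an RA effect of 3.44 and 3.79. The difference of 0.342 between these effects did not pass (exact two-sided permutation p = 0.0688 over 4200 arrangements). Under RA alone the lines differed by 0.272 (exact permutation p = 0.0143, 210 splits), and in vehicle by -0.0705 (exact permutation p = 0.6; 3 against 3 arrays cannot go below 0.1). These permutations count possible duplicates as separate arrays and set aside the pairing of arrays by number. Under RA pair 1 went the other way (0.566 in sh-Control, 0.534 in sh-SIRT1), and 4 pairs are too few for a p under 0.05. The difference under RA was 0.0587 against sh-Control RA array 1 alone (exact permutation p = 0.714), and -0.289 when the gene sets were also called anew with that array alone (exact permutation p = 0.143, the lowest that 1 against 6 arrays can give). It was 0.0219 within slide 4, and 0.202 and 0.194 without sh-Control RA arrays 3 and 4 (exact permutation p = 0.119 for both). The difference of effects was 0.421 without sh-Control vehicle array 1 (exact permutation p = 0.00143). With gene sets from sh-Control cells it was -0.186 (exact permutation p = 0.307). It was 0.129 with sh-Control RA array 1 alone and -0.120 when the sets were also called anew. With gene sets from sh-SIRT1 cells, after normexp correction and without the filter on dim probes it was larger than 0.342, with exact permutation p under 0.05. Gene sets called from 1 line, or with array 1 as the only sh-Control RA array, lean toward the cells they were called from. The permutation holds the sets fixed, so values with such sets do not decide whether the response was larger.

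**Figure D5:**
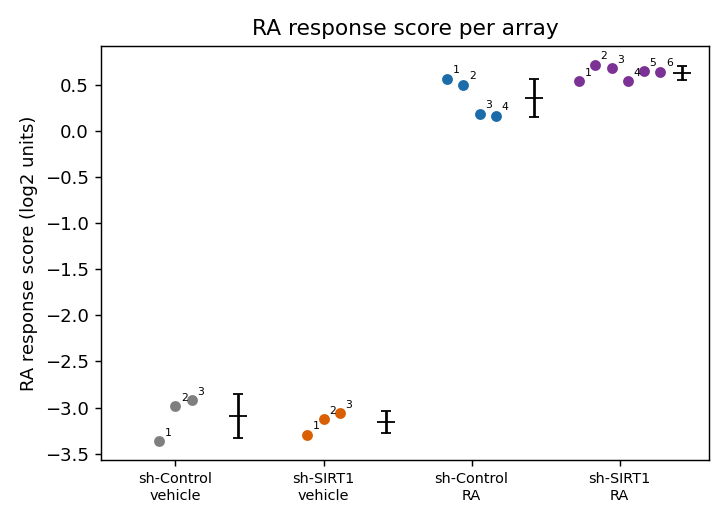
RA response score of each array in log2 units, with the mean ± SD of each group. Under RA the sh-Control arrays lay at 0.163 to 0.566 and the sh-SIRT1 arrays at 0.534 to 0.715.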

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

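Chosen only after the results were seen were the tests of scaling and of a few strong genes for chromosome 8, the tests on Y-linked genes, the 3 tests that weigh the Hox pattern, the splits by pairs for the difference of RA responses, and the fits with sh-Control RA array 1 alone, with the replicate block within treatment and without chromosome 8 genes.

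Genes of chromosome 8 lay higher in sh-SIRT1 cells by a median of 0.36 in vehicle and 0.26 under RA. A gain of the whole chromosome stays open: among 4 parts of the chromosome the last, under RA, had a median of 0.0528, below the 0.0897 of chromosome X in vehicle, the bound written before, but that bound sets a value under RA against one in vehicle, and under RA no other chromosome lay above 0.0036. Scaling of the arrays was argued against because no other chromosome moved by more than 0.0897, and a few strong genes because 75.1% of the genes or more were higher. In the 4 parts the medians were 0.41, 0.44, 0.34 and 0.30 in vehicle and 0.36, 0.41, 0.21 and 0.05 under RA, and on single arrays the median of the chromosome was 0.333 to 0.427 in sh-SIRT1 vehicle and 0.236 to 0.382 in sh-SIRT1 RA against -0.135 to 0.0906 in sh-Control. A gain of part of the chromosome, or in part of the cells, stays open too, as does regulation that depends on SIRT1, which was not tested because hairpin and line history coincide.

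Y-linked genes were low on sh-Control RA arrays 2 to 4. A swap with sh-SIRT1 arrays was argued against, since Sirt1 on the lowest sh-Control RA array lay 1.69 above the highest sh-SIRT1 RA array, and weak signal was argued against by X-linked homologs, whose largest range over all arrays was 0.738. Loss of the Y chromosome from the cells behind these arrays could not be decided. Of 10 probes placed on chromosome Y, 7 were lower there than on each other array, by gaps of 1.36 to 7.14. They included all probes of Ddx3y, Uty, Eif2s3y and Ube1y1. The other 3, of Zfy1, Zfy2 and 1700040F15Rik, were not lower there. Eif2s3y lay at -2.89, -2.53 and -2.51 on these arrays against 0.98 to 2.16 elsewhere, and the imprinted gene Nnat at -6.51, -6.81 and -6.93 against -0.93 on array 1. Beyond loss of the chromosome, no biological explanation was tested.

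Hox genes were higher in sh-SIRT1 cells under RA. Slide was argued against as the whole cause, since the lowest median within a slide was 0.640. For spread between arrays, the exact permutation p was 0.00476 for the mean of the list (difference 1.23), the smallest that 210 splits can give. That p is under 0.05, but the test counts all RA arrays as independent, and some may be duplicates. For example, sh-Control RA arrays 3 and 4 differed by an SD of 0.214 over genes, against 0.736 for arrays 1 and 3. The test also sets aside the pairing by number, and 4 pairs are too few for a p under 0.05. Spread between arrays is thus not excluded, although no sh-Control RA array reached the sh-SIRT1 RA arrays. The make-up of the sh-Control RA group stays open: against its array 1 alone the median was 0.662, but that is a single array. Mean Hox values were -2.43, -2.40, -3.33 and -3.40 on sh-Control RA arrays 1 to 4 and -1.79 to -1.53 on sh-SIRT1 RA arrays. An effect of SIRT1 on Hox genes was not separated from the history of the lines.

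Other splits of the samples were counted for each comparison, the real split included. In vehicle 1 of 10 splits called as many genes (1576, highest other 2), too few splits for a share under 0.05. Chance was argued against for RA in sh-Control cells (1 of 35, 8562 calls, highest other 4172). So it was in sh-SIRT1 cells (1 of 84, 10644 calls, highest other 1). For the hairpins under RA 2 of 100 drawn splits called as many (3706, highest other 4334). The larger split set arrays numbered 1 and 2 of both lines against the rest and so points to a structure of the samples. The fit with replicates as a block within treatment, without sh-SIRT1 RA arrays 5 and 6, called 5126 genes. For the difference of RA responses 2 of 100 drawn splits called as many (657, highest other 924). Both shares are under 0.05, but free splits take arrays as exchangeable, which their correlation across lines goes against. Chance is therefore not excluded for these 2 comparisons. Among splits that part as many replicate pairs, 1 of 4 in vehicle and 1 of 16 under RA called as many, with 0 and 12 as the highest other, and these splits are too few for a share under 0.05. For the difference of responses 128 splits part all 7 pairs, and of 100 drawn 4 called as many (highest other 3558), a share close to 0.05. Of the 3 others, the highest exchanged the lines in all vehicle pairs and another in all RA pairs, which adds the differences between the lines instead of subtracting them and so points to a structure of the samples. The third exchanged all vehicle pairs and RA pair 2.

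In 26 of 318 groups of arrays tested (8.18%) a single array lay far from the others, where chance gives about 1 in 20. On sh-Control RA array 1 these were Fkbp6 (-2.58), Rusc2 (1.93), Gata6 (3.03), Ddx3y (0.23), Nnat (-0.93), Trp53 (1.65) and Sp110 (0.45). On sh-Control RA array 2 they were Sytl3 (-6.64), Plet1 (-0.59), Rpl39l (4.84), Tex101 (-0.48), Gata3 (-0.00456), Peg12 (-0.21), Mesp1 (-5.43), Hsd17b7 (1.14) and the neuroectoderm (-1.71) and p53 target (2.43) lists. On sh-SIRT1 RA arrays they were Rusc2 (1.31), Qprt (1.45), Gata2 (0.10) and Cdkn1a (0.46) on array 1, Kdr (-3.60), Ddx58 (-1.79) and Apol6 (1.71) on array 2, Sox1 (-3.06) on array 5 and Pou5f1 (1.97) on array 6.

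The response to RA differed between the lines, by limma's test of the difference, for the genes that follow (fitted log2 difference, adjusted p). Those of Hoxa5, Hoxd4, Hoxd8, Hoxd12, Foxc2, Nepn, Mmp10, Wif1 and Bhlhe22 rest on signals at background in at least 1 group, so their sizes are not known: normexp correction gave 0.54 for Hoxd4, -0.23 for Hoxd12 and 0.51 for Mmp10. Retinoid genes were Crabp2 (3.70, 5.31e-04), Dhrs3 (2.82, 0.0366) and Rbp4 (1.63, 0.0267), and Hox genes were Hoxa5 (3.45, 0.0124), Hoxd4 (2.67, 0.0125), Hoxd8 (1.44, 0.0225) and Hoxd12 (-2.03, 0.0447). Lineage genes were Meox1 (4.39, 0.0113), Foxc2 (1.67, 0.00307), Plet1 (2.41, 0.0241), Ascl2 (1.14, 0.00914) and Nes (1.31, 0.0245). Members of other lists were Cdkn1a (0.97, 0.0123), Sirt4 (-0.76, 0.00911), Mad2l1 (-0.52, 0.0490), Sp110 (-1.32, 0.0489) and Fbln1 (0.66, 0.0193). Further genes were Nepn (3.40, 0.00823), Mmp10 (3.28, 0.0336), Apol6 (3.06, 0.0179), Slc4a7 (-3.17, 4.39e-05), Wif1 (-2.30, 0.0283), Bhlhe22 (-1.85, 0.0462), Sox18 (-1.69, 0.0390) and Irx2 (-1.58, 0.00911). Over 30 or 31 alternatives the calls of Hoxd12, Bhlhe22, Mad2l1 and Sp110 were lost in 19, 21, 21 and 18. With sh-Control RA array 1 alone, of the genes of this paragraph only Crabp2, Hoxd4, Foxc2, Slc4a7, Wif1 and Irx2 kept their calls. The group is then a single array, so a lost call does not show that a difference went away. Apol6 was 1.43 in that fit, with -0.07 on array 1 against -2.50 to -2.01 on sh-Control RA arrays 2 to 4. With replicates as a block within treatment Hoxd8, Hoxd12, Mad2l1 and Fbln1 lost their calls (adjusted p = 0.0597, 0.0548, 0.0594 and 0.0595). Lists with such a difference had medians of -0.40 (pluripotency), 0.26 (retinoid), 1.10 (Hox), 0.54 (primitive endoderm), 0.25 (trophectoderm), -1.32 (2-cell-like), 0.35 (imprinted), -0.25 (mitosis) and 0.68 (fibroblast), and each call was lost with an estimated correlation.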

How the results depend on the processing

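The fits with sh-Control RA array 1 alone (with either gene set for the score), with the replicate block within treatment and without chromosome 8 genes were chosen only after the results were seen. Causes were not tested unless a fit has fewer arrays or genes by construction. Of 235 calls of named genes, 160 were kept after normexp correction, 222 after quantile normalization, 231 with median scaling, 196 with slide as a fixed block, 234 with slide as a random block, 164 with RA replicates 1 to 3 and 180 with sh-Control RA array 1 alone, where Nnat reversed for RA in sh-Control cells (0.91; 1.25 within slide 4). Of 42 list calls, 0 held with an estimated correlation, 38 after normexp and 33 with array 1 alone. Reversed too were Pou5f1 for RA in sh-Control cells within slide 4 (0.0805), and for the difference of RA responses the primitive endoderm list with array 1 alone (-1.29) and the trophectoderm list within slide 1 (-0.21).

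In vehicle the 1576 calls became 270 (normexp), 975 (slide fixed), 786 (RA replicates 1 to 3), 2372 (array 1 alone), 468 (at least 1 log2 unit) and 739 to 2241 without single arrays. For RA the 8562 calls in sh-Control cells became 4639 (normexp), 2882 (at least 1 log2 unit) and 7113 to 8706 without single arrays, and the 10644 in sh-SIRT1 cells 3523 (at least 1 log2 unit) and 9285 to 11126. Under RA the 3706 calls became 1122 (normexp), 563 (RA replicates 1 to 3), 2030 (array 1 alone), 623 (at least 1 log2 unit) and 2501 to 4286 without single arrays. For the difference of responses the 657 calls became 22 (normexp), 285 (no filter), 92 (slide fixed), 12 (RA replicates 1 to 3), 199 (array 1 alone), 248 (at least 1 log2 unit), 1201 (all probes) and 204 to 1885 without single arrays. Fits that leave out only RA arrays, such as RA replicates 1 to 3 and array 1 alone, leave the vehicle differences unchanged. In vehicle their counts therefore moved only through the estimate of spread that all groups share. Causes of the other shifts were not tested.

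With the replicate number as a block over all arrays, counts were 1378 in vehicle, 2726 under RA and 169 for the difference of responses. With the block within treatment, which follows the pairing assumed, they were 3516, 5126 and 1656. The counts of 5126 and 1656 leave out sh-SIRT1 RA arrays 5 and 6, which have no partner, so they do not rest on the same arrays. Among the calls of named genes and lists that block ended none but those named beside the results.

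The score difference of 0.342 became 0.368 after normexp (exact p = 0.005), 0.366 without filter (exact p = 0.0390), 0.801 with sets from sh-SIRT1 cells (exact p = 0.00119), -0.186 with sets from sh-Control cells (exact p = 0.307), 1.17 for Hox genes as the score (exact p = 0.0195), 0.129 with array 1 alone (exact p = 0.443), -0.120 with the sets called anew on it as well (exact p = 0.614), 0.112 within slide 1 and 0.230 to 0.421 without single arrays. The difference under RA of 0.272 became 0.263 with RA replicates 1 to 3 (exact p = 0.5), 0.0375 with sets from sh-Control cells (exact p = 0.605), 0.0587 with array 1 alone (exact p = 0.714), -0.289 with the sets called anew on it as well (exact p = 0.143), 0.0219 within slide 4 and 0.194 to 0.299 without single arrays. Gene sets called from 1 line lean toward a larger response in that line, as do sets called anew on array 1 toward sh-Control. The permutation holds the sets fixed, so the exact p-values with such sets do not allow for this choice. Sirt1 under RA was -2.39 within slide 2. The series matrix moved nothing, since its values are those used. With 60.3 to 68.6% of probes well above background, folds of dim genes are given as bounds, and fitted differences of such genes are not sizes.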

Other observations

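No test in this part was chosen after its result was seen, but the values by array of the primitive endoderm and fibroblast lists were picked out afterwards.

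Some imprinted genes, which are expressed from 1 parental copy, changed singly between the lines in vehicle. Sgce, a sarcoglycan gene, rose by 1.56 ± 0.28 (adjusted p = 0.00381, 2.94-fold) in sh-SIRT1 cells, while Peg12 fell by 1.03 ± 0.21 (adjusted p = 0.0092) and Phlda2, a placental growth regulator, by 0.57 ± 0.14 (adjusted p = 0.0211). Together with Grb10 this made 1 rise and 3 falls among 24 imprinted genes (4 and 4 adjusted over the list alone), and the list did not pass (median 0.02, adjusted p = 0.991). Nap1l5, imprinted as well and at least 1.18-fold higher, lies outside the list and is not counted. Grb10 lay at 2.99 ± 0.37 (SD, n = 3) and -0.26 ± 0.08 (n = 3) in sh-Control and sh-SIRT1 cells in vehicle and at 3.47 ± 0.81 (n = 4) and -0.14 ± 0.19 (n = 6) under RA; within slides 1 and 3 the vehicle difference was -3.63 and -3.01, and within slides 1, 2 and 4 the difference under RA was -2.88, -3.54 and -4.34.

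In vehicle the trophectoderm genes Ascl2 and Ets2 fell by 0.80 ± 0.15 and 0.55 ± 0.10 (adjusted p = 0.00611 and 0.00461), and the mesoderm gene Mesp1, which marks early cardiac progenitors, rose by 0.97 ± 0.23 (adjusted p = 0.0191). Gata3 was at least 1.72-fold higher. Primitive endoderm genes varied among the RA arrays: their mean was 1.58, -0.156, -1.17 and -1.17 on sh-Control RA arrays 1 to 4 and 0.111, 0.328, -0.481, -0.655, -0.512 and -0.495 on sh-SIRT1 RA arrays 1 to 6. Fibroblast markers lay at 0.0654, 0.527, -1.16 and -1.24 and at 0.405, 0.573, -0.302, -0.239, -0.315 and -0.141 on the same arrays.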
